A study of Homo sapiens with 4 samples.

How the data were processed

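Total RNA of HEK293T cells was sequenced in 4 libraries, 2 labelled Control and 2 labelled DHX29-KO, made with the TruSeq Stranded Total RNA kit on an Illumina NextSeq sequencer, per the labels' protocols. The submitters' processing notes name Trim Galore 0.6.10, HISAT2 2.2.1, featureCounts from Subread 2.0.1 and the hg38 build, without further settings. The authors deposited 1 table of whole-number read counts per gene, with 66023 rows and 1 column per library, and no normalization. Columns were matched to libraries by their names, which give the group and the replicate number.

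How reads were counted was examined from the values. In 47 single-exon non-coding genes that lie inside an exon of a coding gene on the opposite strand, the median read density was 0.765 of that of the coding gene, so most of these genes took reads from the opposite strand. In 34 such genes on the same strand the median was 0.22, lower than sharing of all overlapping reads would give, so the counting rule for overlaps is not settled. In 12 pseudoautosomal genes the count of the Y row over that of the X row had a median of 1.01, so reads with several places were not discarded; whether they were counted at each place or spread between places is not settled. Antisense genes, overlapping genes, alternate-haplotype copies and paralogs can therefore share reads, and their single values are uncertain. The total count per library, from 36583703 to 52231152, can differ from the number of reads.

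Rows were matched by identifier, without its version, to GENCODE 29 on GRCh38, the assembly also called hg38; 56927 rows matched and 9096, mostly alternate copies, did not. Coordinates and gene types come from that annotation. Members of gene lists were taken from the matched row of each symbol. G+C at codon position 3 was computed on the longest coding sequence of each gene, which covered 98.57% of the 14488 protein-coding genes tested.

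The 2 groups were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (estimateDisp, glmQLFit, glmQLFTest) with TMM normalization and filterByExpr (minimum count 10, minimum total 15), which kept 23922 genes. The design held the group alone, p-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of F. Gene lists, 31 in number and fixed before the data were examined, were tested with camera of limma 3.58.1 at its preset correlation of 0.01 where at least 5 members were measured, which held for 30, with adjustment over lists. Members were also adjusted over the list alone. Camera with an estimated correlation, given beside the main test, rests on the few degrees of freedom that 4 libraries leave, so it has little power. CPM values use TMM-scaled totals of the tested genes, and means are given with the SD of 2 libraries.

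Genes named in the text follow a rule fixed before the data were examined. It takes DHX29 and the 10 largest rises and 10 largest falls among genes called, with a mean of at least 5 CPM, both DHX29-KO libraries on the same side of both Control libraries and a gene symbol rather than a clone name. It then takes up to 4 called members with the smallest p from each list called by camera or holding at least 3 called members, up to 2 of the most abundant members of each other list, and 3 genes of the lowest and of the highest GC3 class. Some genes that this rule takes are not reported here. Other genes are named where a count of called members is small or as singled out after their values were seen.

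The procedure was tested on simulated counts with the means and library sizes of the DHX29-KO against Control comparison. Among 23476 simulated genes, it called 20% of genes changed 1.25-fold, 76% of those changed 1.5-fold, 94% of those changed 2-fold and 100% of those changed 3-fold, with 1 false call among 146. Camera gave p under 0.05 for 4 of 200 unchanged lists. Genes were simulated independently and with the same dispersion, so these rates do not cover lists of genes that move together.

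Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, RLE normalization, library totals alone, other low-count filters, other edgeR settings, stricter thresholds, camera with an estimated correlation, fry, a replicate block and leaving out each library. Fits on GENCODE 29 rows alone, on protein-coding genes alone, without chromosomes 3, 4, 13 and 17, and without ZNF genes were added after the data were seen. Medians along chromosomes used coding genes in bins of 10 Mb with at least 12 genes, with bootstrap intervals over genes. Sequence shared between genes was counted as 50-mers of GENCODE 29 transcripts, at every position in place of the sampled positions of a first run, in Python 3.11 with NumPy and pandas.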

Results

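RNA sequencing was used to compare gene expression in HEK293T cells with and without a guide RNA against DHX29, a DExH-box RNA helicase that binds the 40S ribosomal subunit and assists scanning on structured messenger RNA leaders. HEK293T is a human embryonic kidney line that carries the SV40 large T antigen. Per the labels, cells expressing the Cas9 nuclease had received either a control guide RNA vector or one directed against DHX29, which gave 2 Control and 2 DHX29-KO libraries. The total count was 45980193 in Control 1, 52231152 in Control 2, 36583703 in DHX29-KO 1 and 49953893 in DHX29-KO 2. The labels do not say that the replicates were separate cultures, or whether each group derives from a single clone, so p-values here measure only the spread between these 4 samples, which may be technical.

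The targeted gene was lower in both DHX29-KO libraries. DHX29 (ENSG00000067248.9, chromosome 5, 55256245 to 55307722, minus strand, GRCh38) had 1590 and 2113 reads in the Control libraries and 575 and 737 in the DHX29-KO libraries. These counts correspond to 34.3 and 39.6 CPM, the usual unit of counts scaled by library size, in Control and to 15.96 and 15.02 CPM in DHX29-KO. DHX29 fell by 1.26 on the log2 scale (SE 0.0792, n = 2 and 2), with an adjusted p of 1.82e-04 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Transcripts of an edited locus remain countable, so this level does not measure how much DHX29 protein was left.

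**Figure D1:**
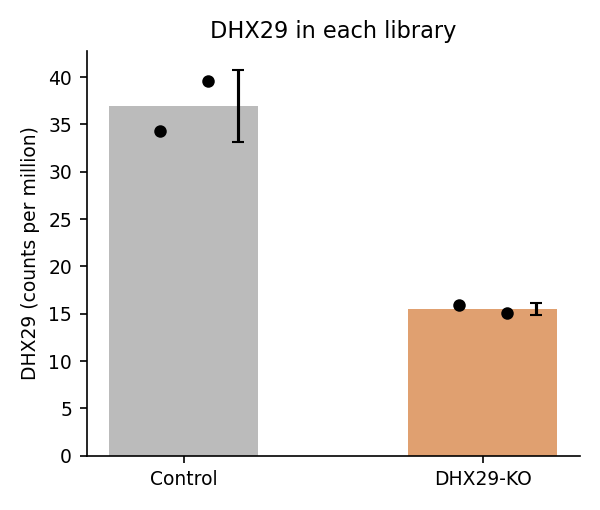
DHX29 expression in CPM (vertical axis) in the Control and DHX29-KO groups; bars are means, dots are the 2 libraries of each group and error bars are the SD. The DHX29-KO libraries sit at 15.96 and 15.02 CPM, below the Control libraries at 34.3 and 39.6 CPM.

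The comparison of DHX29-KO with Control asks which transcripts differ when DHX29 is targeted. Among genes averaging at least 5 CPM, the largest rises were in the long non-coding RNA LINC00667, the zinc finger gene ZNF329, the sorting nexin gene SNX19 and the protocadherin gene PCDH10, and the largest falls were in the cancer-testis antigen gene MAGEA1, FAM133A, SPATA13 and DPYSL4. Clustered protocadherin genes, many genes named ZNF and several interferon-stimulated genes rose, whereas the neurofilament gene NEFL, the synaptic vesicle gene SYP and some ribosomal protein genes fell. Most shifts were small: the median absolute log2 fold change of the genes called was 0.38.

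Of 23922 genes tested, 1265 were higher and 1393 lower in DHX29-KO at an adjusted p under 0.05, with DHX29 left out. Among them, 246 were higher and 118 lower by at least 2-fold. Protein-coding genes made up 977 of the higher and 1197 of the lower genes. Each row was counted as a gene, and rows outside GENCODE 29 made up 2112 of those tested, 70 of the higher and 106 of the lower. The balance of the 2 directions depended on the scaling: with library totals alone, 967 genes were higher and 2215 lower, so 30.4% of the calls were rises in place of 47.6%. Without DHX29-KO 1 or without DHX29-KO 2, which leaves 1 sample in that group, fewer genes were called. Genes named by rule that lost their call in both fits included EIF3M, HK2, ENO2 and LUM. The losses were not limited to small folds, as LUM had a log2 fold change of 0.88 with all libraries.

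LINC00667 (ENSG00000263753.6, chromosome 18, 5237826 to 5246508) rose 5.38-fold, from 3.03 ± 0.413 CPM to 16.3 ± 0.567 CPM (SD, n = 2 per group; log2 fold change 2.43, SE 0.106, adjusted p = 5.04e-05). ZNF329 (ENSG00000181894.14, chromosome 19, 58126252 to 58155110) rose 3.58-fold, from 3.45 to 12.4 CPM. SNX19 rose by a log2 fold change of 1.55 and PCDH10, a cell adhesion gene on chromosome 4, by 1.51. The other large rises were in the pseudogene MSL3P1 (1.31), the laminin gene LAMA2 (1.28), the antiviral gene SAMD9 (1.26), TEX14 (1.24) and ZNF605 (1.19). SAMD9 differed between the Control libraries, at 2.46 and 4.93 CPM, and was at 9.08 and 8.81 CPM in DHX29-KO. RPP21 also qualified (log2 fold change 1.34), but through a row for an alternate-haplotype copy (ENSG00000243009.5). The row of RPP21 on the primary assembly (ENSG00000241370.5) had a log2 fold change of -1.04 with an adjusted p of 0.119, so its direction is uncertain.

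MAGEA1 (ENSG00000198681.6, chromosome X, 153179285 to 153183880) fell from 36.7 ± 1.28 CPM to 9.17 ± 1.27 CPM (SD, n = 2 per group; log2 fold change -1.99, SE 0.0875, adjusted p = 5.04e-05). FAM133A, also on chromosome X, fell from 20.8 to 6.06 CPM (log2 fold change -1.78). Falls of more than 2-fold followed in SPATA13 (-1.62), DPYSL4 (-1.49), NAP1L3 (-1.41), SNAI2, which encodes the transcription factor SLUG (-1.40), CRMP1 (-1.26) and MPHOSPH8 (-1.25). MPHOSPH8 encodes a chromodomain subunit of the HUSH silencing complex and fell from 18.5 ± 1.62 CPM to 7.75 ± 0.564 CPM (SD, n = 2 per group). MPHOSPH8 and SPATA13 lie on chromosome 13, where coding genes as a set were lower, as given below. CNOT3 qualified (-1.30) only through an alternate-haplotype copy (ENSG00000277600.4), and its row on the primary assembly (ENSG00000088038.17) had a log2 fold change of -0.02 with an adjusted p of 0.932.

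Clustered protocadherins, cell adhesion genes in tandem arrays on chromosome 5, showed the largest shift of any list. Of 35 measured members, 34 rose and none fell over all genes, and 35 rose when adjusted over the list alone. The median log2 fold change was 0.74, and camera with its preset correlation gave an adjusted p of 2.66e-21, against an adjusted p of 0.727 with an estimated correlation. The single-exon beta genes had low levels and the largest folds: PCDHB16 went from 0.211 to 1.73 CPM (8.13-fold), PCDHB8 rose 7.08-fold and PCDHB2 6.07-fold, from 0.658 to 3.98 CPM. The 22 measured gamma genes, among them PCDHGA1 (log2 fold change 0.98), rose by 0.48 to 0.98 but share constant exons, so their rows are not independent.

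Zinc finger genes named ZNF, many of which encode KRAB repressors, were higher as a set. Of 457 measured, 122 rose and 12 fell over all genes, and 147 rose and 23 fell when adjusted over the list alone. The median log2 fold change was 0.13 (camera adjusted p = 1.85e-07; adjusted p = 0.727 with an estimated correlation). ZNF772 rose from 17.5 to 35.0 CPM, ZNF134 by a log2 fold change of 0.81 and ZNF229 by 2.11. The genes that fell included ZNF700 (-1.76), ZNF681 (-1.74), ZNF492 (-1.62) and ZNF91 (-1.48), which were singled out after their values were seen. Genes of this family resemble one another, so single values can carry reads of related copies.

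Interferon-stimulated genes were higher as a set, with 5 of 26 measured members higher over all genes, 8 when adjusted over the list alone, and none lower. The median log2 fold change was 0.15 (camera adjusted p = 0.00533; adjusted p = 0.727 with an estimated correlation). IFIH1, which encodes the double-stranded RNA sensor MDA5, rose from 0.826 ± 0.132 CPM to 3.45 ± 0.133 CPM (SD, n = 2 per group). IFI44L rose by a log2 fold change of 2.72 from a level near 0.1 CPM, SAMD9 by 1.26, and HERC5 and HERC6 by 0.45 and 0.66. HERC5 and HERC6 lie on the part of chromosome 4 that was higher as a whole. NF-kappaB targets were not called by camera (2 of 15 higher, NFKB1 and BIRC3; 2 when adjusted over the list alone), but fry, which asks whether a set moves one way without comparing it with other genes, gave an adjusted p of 0.0211 for a rise.

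Neuronal genes expressed in this line were lower as a set (median log2 fold change -0.10, camera adjusted p = 0.0455; adjusted p = 0.727 with an estimated correlation). Of 19 measured, 6 fell and 2 rose over all genes, and 7 fell and 2 rose when adjusted over the list alone. The neurofilament gene NEFL fell from 64.7 ± 1.78 CPM to 37.4 ± 2.71 CPM (SD, n = 2 per group). The stathmin gene STMN3 fell from 29.9 to 15.8 CPM and the synaptic vesicle gene SYP from 17.9 to 9.34 CPM. ELAVL2, NCAM1 and CHGB also fell, whereas SYT1 and ENO2 rose by 0.36 and 0.45. The call was lost with library totals alone (median -0.15) and without Control 1, Control 2 or DHX29-KO 1, where the medians were -0.09, -0.07 and -0.22.

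All 13 subunits of eIF3, the initiation factor that binds the 40S subunit, had negative values with a median of -0.11. EIF3F, EIF3L, EIF3M and EIF3D fell by 0.26, 0.22, 0.19 and 0.18 on the log2 scale, and 6 subunits fell when adjusted over the list alone (camera adjusted p = 0.00533; adjusted p = 0.836 with an estimated correlation). Of 32 other initiation factors, 5 fell and 1 rose over all genes, and 6 fell and 1 rose when adjusted over the list alone (median -0.09, camera adjusted p = 0.0455; adjusted p = 0.836 with an estimated correlation). Those that fell were EIF4EBP1, EIF4EBP2, PABPC1, EIF6 and EIF4B, and the cap-binding protein gene EIF4E on chromosome 4 rose by 0.19. Of 79 cytosolic ribosomal protein genes, 7 fell and none rose, over all genes and when adjusted over the list alone (median -0.06, camera adjusted p = 0.017; adjusted p = 0.852 with an estimated correlation). RPL29 fell by 0.48, RPL21 by 0.44, RPL10 by 0.39 and RPS16 by 0.39 on the log2 scale. RPL29, RPL14 and RPSA lie on chromosome 3 and RPL21 on chromosome 13, and ribosomal protein genes share reads with processed pseudogenes. Without DHX29-KO 1, none of these 3 lists was called (medians -0.11, -0.08 and -0.04) and 5 lists in all were called in place of 8. The ribosomal protein call was also lost without Control 1 (median -0.01), and that of the other initiation factors without any 1 of the 4 libraries.

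Of the other lists fixed before the data were examined, the fibroblast and muscle markers described below were called by camera and the rest were not. Among other DExH and DEAD-box helicases, 1 of 32 rose and 1 fell, also when adjusted over the list alone; the abundant DDX17 and DDX5 had log2 fold changes of 0.01 and 0.13 with adjusted p of 0.915 and 0.146. In deadenylation, decapping and repression factors, 2 of 36 rose and 4 fell (3 and 5 adjusted over the list alone), with CNOT10, DCP1A, LSM7 and PAN3 lower, at log2 fold changes of -0.39, -0.35, -0.34 and -0.32. Of nonsense-mediated decay factors, 1 of 16 rose (SMG8, 0.23) and 2 fell (UPF3A, -0.58, and SMG9, -0.26), with the same counts adjusted over the list alone. Of transcripts sensitive to that pathway, SNHG8 (0.29) and SNHG6 (0.28) rose and EPHB4 (-0.19) fell, also the count of 2 and 1 of 18 adjusted over the list alone.

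Among integrated stress response targets, 3 of 40 rose and 3 fell (3 and 3 adjusted over the list alone): the amino acid transporter genes SLC7A1 (-0.43) and SLC7A5 (-0.37) and ALDH1L2 (-0.32) fell, and SLC7A11 (0.26) was among those that rose. Of genes of the unfolded protein response, none of 24 rose and 2 fell (1 and 5 adjusted over the list alone), and the chaperone genes CANX and CALR had log2 fold changes of -0.15 and 0.15 with adjusted p of 0.0977 and 0.0688. Of cholesterol synthesis genes, 1 of 24 rose (SC5D, 0.50) and 4 fell (4 and 8 adjusted over the list alone), with FDFT1 (-0.23) and HMGCS1 (-0.18) among them. Of NRF2 targets, 2 of 21 rose and 4 fell (2 and 5 adjusted over the list alone): heme oxygenase HMOX1 went from 30.2 to 18.2 CPM, NQO1 from 5.14 to 9.10 CPM, TKT fell by 0.47 on the log2 scale and GCLM by 0.24. Of glycolysis and hypoxia genes, 3 of 31 rose and 4 fell (4 and 5 adjusted over the list alone), with the hexokinase genes HK1 (-0.49) and HK2 (-0.25) lower and ADM (0.48) higher. Of heat shock chaperones, none of 19 rose and 3 fell (1 and 3 adjusted over the list alone), namely HSPH1, HSPA1B and HSPA1A, of which the last pair are near-identical copies.

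Growth and matrix lists were likewise mixed. Of immediate early genes, 3 of 27 rose and 2 fell (5 and 3 adjusted over the list alone), with MYC (-0.32) and SRF (-0.32) lower and CYR61 (0.74) and ATF3 (0.32) higher. Of TGF-beta targets and matrix genes, 3 of 27 rose and 8 fell (4 and 8 adjusted over the list alone): the basement membrane collagen genes COL4A2 (-0.70) and COL4A1 (-0.66), both on chromosome 13, fell, and LOX (0.75) and SKIL (0.37) rose. Of G1/S genes, 2 of 36 rose and 3 fell (3 and 3 adjusted over the list alone), with MCM4 (0.28) higher and CCNE1 (-0.30), POLD1 (-0.24) and RRM2 (-0.22) lower. Of G2/M genes, 2 of 38 rose and 3 fell (6 and 4 adjusted over the list alone), with MAD2L1 (0.25) and KIF2C (0.24) higher and CKAP2 (-0.33) and UBE2C (-0.19) lower. Of p53 targets, 1 of 25 rose and 1 fell, also when adjusted over the list alone, and MDM2 had a log2 fold change of 0.12 with an adjusted p of 0.139 and CCNG1 one of -0.14 with 0.113. Of lysosome and autophagy genes, 4 of 28 rose and 3 fell (5 and 5 adjusted over the list alone), with LAMP1 (-0.50) and NPC2 (-0.29) lower and GABARAPL1 (0.33) and FLCN (0.29) higher. Of nuclear-encoded oxidative phosphorylation genes, 1 of 59 rose (NDUFC1, 0.49) and 4 fell (1 and 4 adjusted over the list alone), with NDUFA10 (-0.26), COX8A (-0.22) and UQCRC1 (-0.22) among them. Of replication-dependent histone genes, 3 of 47 rose (HIST1H3F, 0.56, HIST1H2BG and HIST1H2AE) and 1 fell (HIST1H4I, -0.44), against 3 and 0 adjusted over the list alone. None of 13 mitochondrially encoded protein genes passed in the main edgeR fit, DESeq2 or limma-voom, nor in the main fit when adjusted over the list alone. In that fit 1 had an unadjusted p under 0.05, and MT-CO1 and MT-CO3 had log2 fold changes of -0.12 with adjusted p of 0.363 and 0.327. Over the alternatives these ranged from -0.23 to -0.003 and from -0.22 to -0.016, and each kept its outcome in 15 of 17.

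Markers of other cell types were near the floor. Fibroblast and muscle markers were higher as a set (camera adjusted p = 0.017; adjusted p = 0.727 with an estimated correlation), with 2 of 7 measured members higher over all genes and 3 when adjusted over the list alone. The 2 were the mesenchymal transcription factor gene TWIST1, from 2.19 to 4.51 CPM, and the proteoglycan gene LUM, from 1.08 to 1.99 CPM. COL1A1 stood at 2.11 and 1.71 CPM in Control and at 2.14 and 2.34 CPM in DHX29-KO. MYH3 and COL1A1 lie on chromosome 17 and PDGFRA on chromosome 4, which were higher as a whole, whereas TWIST1 and LUM lie on chromosomes 7 and 12. None of 6 blood cell markers and none of 3 endothelial or squamous markers passed in edgeR, DESeq2 or limma-voom, nor in edgeR when adjusted over the list alone or at an unadjusted p under 0.05; CD68, CD8A, SFN and DSG3 all stayed under 3 CPM in every library. Of 21 non-coding RNAs that follow RNA quality and ribosomal RNA depletion, 3 rose and none fell over all genes, and 5 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0522). RNU1-1 rose by a log2 fold change of 0.53, SNORA73B by 0.52 and SCARNA2 by 0.54, and 7SL-like rows took 10.06% and 10.02% of the counts in Control and 9.75% and 12.39% in DHX29-KO. Mitochondrial genes took 2.01% and 1.89% in Control and 2.33% and 1.75% in DHX29-KO. Protein-coding genes took 57.43% and 57.91% in Control and 54.36% and 55.08% in DHX29-KO, and the 10 most abundant genes of each library took 20.27% and 20.31% against 21.74% and 22.94%.

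**Figure D2:**
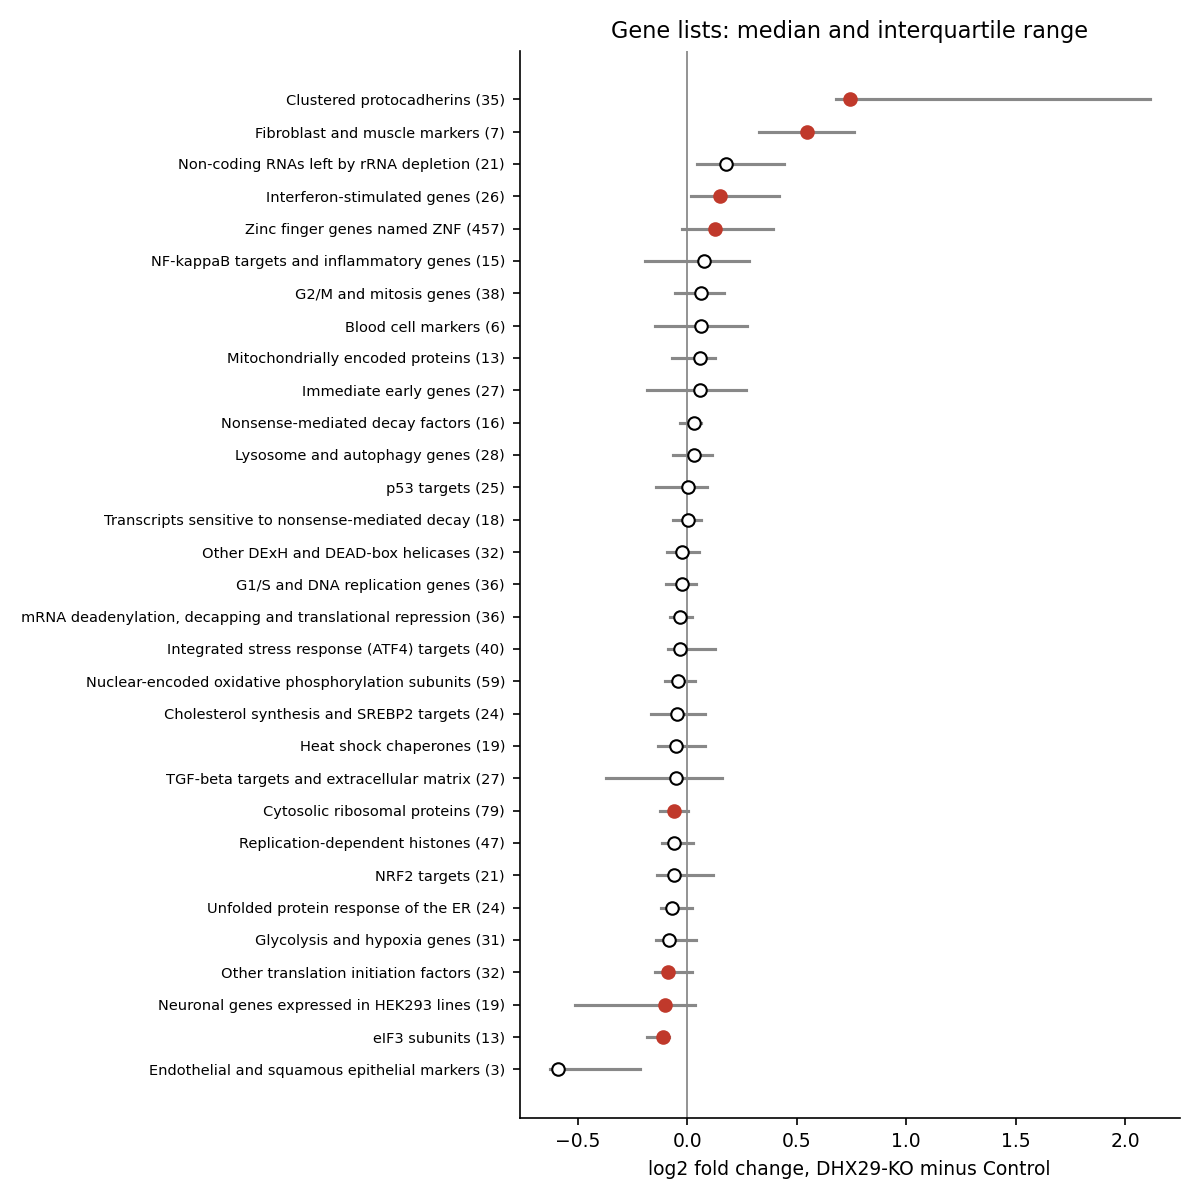
Median log2 fold change, DHX29-KO minus Control (horizontal axis), of each gene list, with the number of measured members in parentheses; lines are interquartile ranges and filled red dots mark the 8 lists called by camera with the preset correlation. Clustered protocadherins have the highest median, 0.74, and eIF3 subunits the lowest of the called lists, -0.11.

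Coding genes with little G+C at their synonymous codon positions (GC3) tended to be higher and GC3-rich genes lower in DHX29-KO. Among the 3 genes with the smallest p in the lowest GC3 class, SEC31A, a COPII coat gene on chromosome 4, rose from 33.1 to 54.0 CPM, and FAM133A and DHX29 itself fell. In the highest GC3 class, ZSCAN18 rose from 1.71 to 7.29 CPM and RPRM, a p53-induced cell cycle gene, from 1.46 to 7.03 CPM, whereas FAM84B fell from 8.30 to 1.59 CPM. Across 5 classes of about 2856 coding genes each, the median log2 fold change went from 0.04 in the lowest class to 0.01, -0.01, -0.05 and -0.08 in the highest; with library totals alone, the median of the lowest class was -0.01. The share of genes called higher went from 11.2% to 2.66%, and the share called lower from 5.32% to 12.7%.

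Across 14281 coding genes, which are not independent replicates, Spearman's rho between GC3 and the log2 fold change was -0.22. The same rho was -0.10 for Control 2 minus Control 1 and -0.04 for DHX29-KO 2 minus DHX29-KO 1, so a smaller trend of this kind was present without a difference in DHX29. Camera gave an adjusted p of 4.33e-04 for both the lowest and the highest class. With an estimated correlation the adjusted p was 0.236 for the lowest class and 0.0262 for the highest. The trend was not specific to codons: rho was -0.21 for the G+C of the 3' UTR and -0.16 for that of the 5' UTR.

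**Figure D3:**
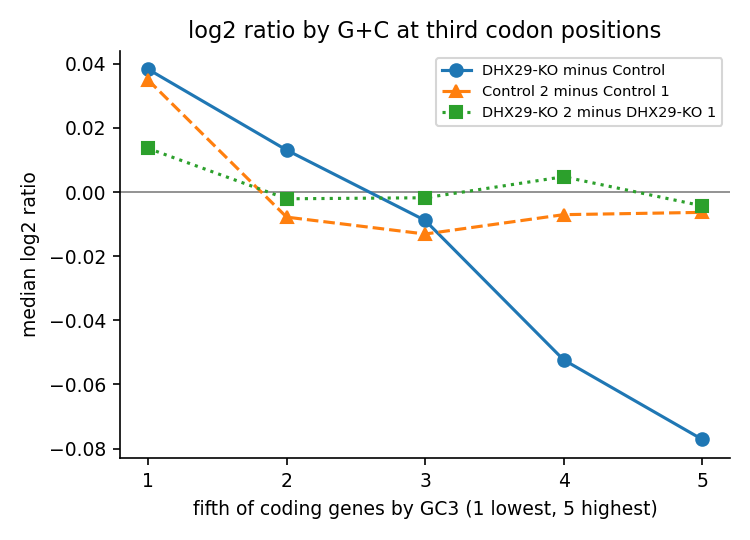
Median log2 ratio (vertical axis) in 5 classes of coding genes ordered by GC3 (horizontal axis), for DHX29-KO minus Control and for the differences between the 2 replicates of each group. The DHX29-KO minus Control median goes from 0.04 to -0.08, while that of Control 2 minus Control 1 goes from 0.03 to -0.01.

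Genes also shifted by position, a comparison added after the values were seen. Coding genes of chromosome 13, leaving out ZNF genes and clustered protocadherins, had a median log2 fold change of -0.33, with 130 of 252 lower and 6 higher. Those of chromosome 4 had a median of 0.21, with 169 of 521 higher and 9 lower, and those of chromosome 17 a median of 0.10, with 110 of 880 higher and 20 lower. On chromosome 4, medians of 10-Mb bins ran from 0.28 to 0.43 between 70 and 180 Mb, and the bin from 50 to 60 Mb had a median of 0.18 (95% bootstrap interval 0.13 to 0.25). On chromosome 3, the bin from 50 to 60 Mb had a median of -0.39, that from 30 to 40 Mb one of -0.29 and that from 60 to 70 Mb one of -0.23. On chromosome 13, the bin from 70 to 80 Mb had a median of -0.03 (interval -0.08 to 0.0009), and the other bins ran from -0.59 to -0.25. Elsewhere, 1 bin lay further than 0.2 from 0, that from 190 to 200 Mb of chromosome 1 (0.25). Camera gave an adjusted p of 3.99e-18 for chromosome 13, 5.17e-18 for chromosome 4 and 2.23e-07 for chromosome 17; with an estimated correlation the adjusted p was 0.0886, 0.0402 and 0.0402. Chromosome 3 as a whole did not pass (median -0.05, adjusted p = 0.0642). Smaller falls passed for chromosomes X (median -0.07, 77 of 492 lower and 17 higher, adjusted p = 0.0102), 19 (-0.08, 105 of 861 lower and 23 higher, 0.0323) and 20 (-0.06, 43 of 374 lower and 7 higher, 0.0323), with adjusted p of 0.0998, 0.192 and 0.137 with an estimated correlation. The trend with G+C was not removed from these chromosome medians. Called genes named above that lie on chromosome 3 between 30 and 70 Mb are CNOT10, DCP1A, TKT, UQCRC1, RPL29, RPL14 and RPSA. On chromosome 4 between 70 and 180 Mb they are PCDH10, HERC5, HERC6, NFKB1, EIF4E, SEC31A, SNHG8, SLC7A11, MAD2L1 and NDUFC1. Chromosome 13 holds MPHOSPH8, SPATA13, RPL21, PAN3, UPF3A, SLC7A1, HSPH1, COL4A1, COL4A2, CKAP2 and LAMP1, and chromosome 17 holds TEX14, SMG8 and FLCN. Called genes named above also lie on chromosomes X, 19 and 20, such as MAGEA1 and FAM133A on X, and are not listed.

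**Figure D4:**
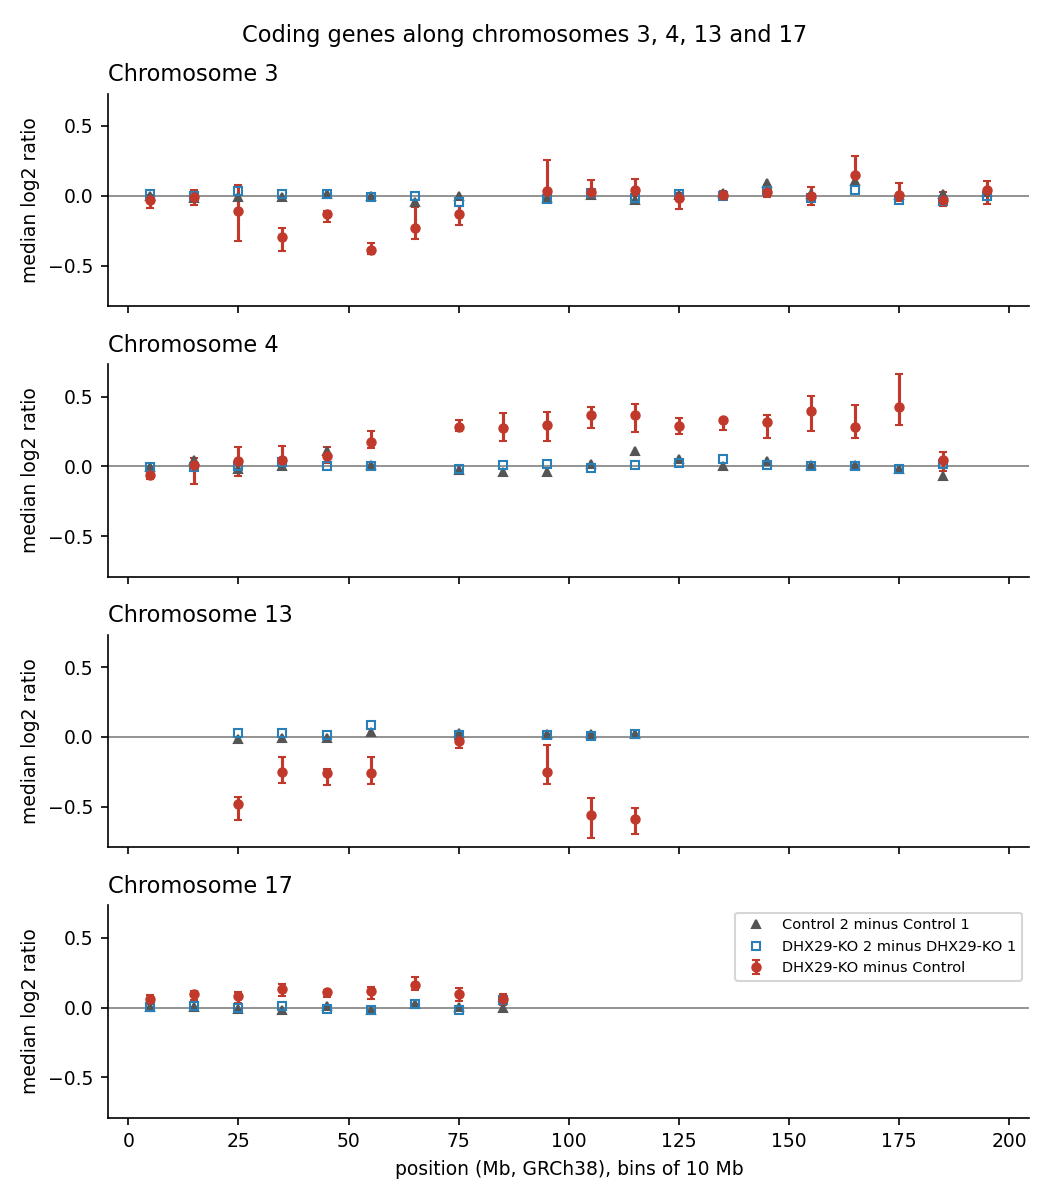
Median log2 ratio of coding genes (vertical axis) in 10-Mb bins along chromosomes 3, 4, 13 and 17 (horizontal axis, Mb), for DHX29-KO minus Control with 95% bootstrap intervals over genes and for the replicate differences within each group. Bins of chromosome 4 between 70 and 180 Mb lie between 0.28 and 0.43, and bins of chromosome 13 reach -0.59, while no bin of the genome lies further than 0.132 from 0 in the replicate differences.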

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

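The fits limited to GENCODE 29 rows, to protein-coding genes, to chromosomes other than 3, 4, 13 and 17, and to genes other than ZNF genes were chosen after the data were seen. The fall of DHX29 kept its direction and its call in all 17 alternatives, from -1.36 to -1.15. Against 1265 genes higher and 1393 lower, DESeq2 called 713 and 769, and the cause was not tested. Stricter criteria by construction gave 426 higher and 452 lower genes at an adjusted p under 0.01, 246 and 118 at 2-fold or more, and 301 and 224 against a 1.2-fold change. Library totals alone, which change only the scaling, gave 967 higher and 2215 lower genes. The median log2 fold change of all genes tested was then -0.043, in place of 0.0032. With no low-count filter the counts were 1856 and 2463, and the cause was not tested. Leaving out 1 library at a time, which leaves an arm whose lone sample is assumed to vary like the other group, gave 598 to 1412 higher and 621 to 1392 lower genes. Without chromosomes 3, 4, 13 and 17, 988 genes were higher and 1078 lower. GENCODE 29 rows alone gave 1483 higher and 1648 lower genes, and protein-coding genes alone 1643 and 1630. Genes other than ZNF genes gave 1129 and 1333. The robust setting of edgeR gave 1564 and 1823, and the causes were not tested. Of 113 called genes named by rule, 45 were no longer called without at least 1 of the libraries.

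In place of 8 lists, 4 were called with at least 1 CPM in 2 libraries and 5 with fry. Fewer were also called with 1 library left out, and the cause of these losses was not tested. Camera with an estimated correlation called 0. That setting tests each list on the few degrees of freedom that 4 libraries leave, so it has little power. Its larger adjusted p therefore does not by itself show that genes of a list move together. Fry called 4 of the 8, at adjusted p from 0.0414 to 0.0494, and NF-kappaB targets. It did not call the ZNF, eIF3 and other initiation factor lists (fry adjusted p = 0.0598 for each) or the ribosomal protein list (0.44). The estimated correlation was -0.015, -0.035 and -0.13 for the interferon, neuronal and fibroblast lists. A correlation above the preset 0.01 was therefore not why camera lost those calls. For the other called lists the estimate ran from 0.042 to 0.69. Without chromosomes 3, 4, 13 and 17, 6 lists were called: neuronal genes had an adjusted p of 0.0643, and fibroblast and muscle markers, with 4 members left, were not tested. The median of the lowest GC3 class, 0.038, was past the threshold of neither fry (adjusted p = 0.143) nor camera with an estimated correlation (adjusted p = 0.236). DDX17, not called at 0.01, had -0.034 with library totals alone, -0.0059 with no low-count filter, -0.0038 without Control 1, -0.0011 without DHX29-KO 1 and 0.030 without Control 2; CD68, not called at -0.11, ranged from -0.32 without DHX29-KO 1 to 0.11 without DHX29-KO 2. The labels number the replicates but do not pair them, and deviations of libraries with the same number correlated by 0.027 across 11289 genes. With the replicate block, 1183 genes were higher and 1253 lower, and 7 lists were called, without the other initiation factors (adjusted p = 0.0645). Single genes near 1 CPM rest on few counts per library, which limits the precision of their folds. Of genes not called in the main fit, CANX and CALR each kept that outcome in 12 of 17 alternatives, CCNG1 in 14 of 17 and DDX5 in 15 of 16. Of genes called, SCARNA2 kept its call in 12 of 16, with values from 0.33 to 0.80. HIST1H4I kept its call in 10 of 17, with values from -0.58 to -0.27.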

Other observations

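The tests of chromosome 13 and 4 copy number, of the other genes of chromosome 19 and of beta protocadherin sequence were chosen after the result was seen; the other tests were set out before their values were computed. The bound on shared beta sequence was set at 15% after no beta gene met a bound of 5%, and the comparison of single-exon genes with the replicate differences was added after those genes had met the bound set for them. Chromatin silencing genes, singled out after their values were seen, moved apart. MPHOSPH8 had a log2 fold change of -1.25, whereas FAM208A (TASOR), its partner in the HUSH complex, which lies where chromosome 3 genes were lower as a set, rose from 128 and 136 CPM to 206 and 211 CPM (log2 fold change 0.66, SE 0.0505, edgeR adjusted p = 3.66e-04). MORC2, an ATPase that acts with HUSH, rose by 0.78 (SE 0.0634, adjusted p = 4.56e-04). PPHLN1, SETDB1 and ATF7IP, which encode further members or partners of this pathway, had log2 fold changes of 0.02, 0.07 and -0.10 with adjusted p of 0.856, 0.41 and 0.253. TRIM28, the corepressor of KRAB zinc finger proteins, fell by 0.21 (adjusted p = 0.0297).

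Other single-exon coding genes with large changes included RPRM, CENPBD1 (log2 fold change 1.12), CEBPD (1.89) and VN1R1 (1.83), which rose, and NAP1L3 (-1.41) and CDR1 (-1.19), which fell. Outside the beta cluster, PCDH17, PCDH7 and PCDH10 rose by 0.97, 0.86 and 1.51, and PCDH1 fell by 1.72 on the log2 scale.

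Genes lying together on chromosomes 3, 4 and 13 shifted the same way. Across 13980 coding genes, the log2 fold change correlated with the median of 10 neighbouring genes by 0.284, against at most 0.0342 in 1000 shuffles of gene positions and 0.0257 and 0.0129 for the replicate differences, and it was 0.156 without chromosomes 3, 4, 13 and 17, so part of it lies elsewhere. A trend of the libraries with G+C, length or expression does not account for the chromosome 13 shift, whose median was -0.36 (95% bootstrap interval -0.40 to -0.32) after its removal. The chromosome 4 median was then 0.17. Chromosome 3 and the correlation between neighbours were not examined after removal of that trend, so it may hold part of that correlation. In the lower, middle and upper expression classes, chromosome 13 had medians of -0.34, -0.36 and -0.26 and chromosome 4 had medians of 0.31, 0.21 and 0.16. A candidate explanation is a difference in DNA copy number between the control and DHX29-KO cells, which no DNA measurement here tests and which could arise if each group came from a single clone, and an effect of DHX29 loss on these regions stays open.

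ZNF genes were higher mainly on chromosome 19, where 83 of 206 rose and 5 fell with a median of 0.23, against a median of 0.06 for 240 on other chromosomes. More copies of the whole of chromosome 19 do not account for this, as its other coding genes had a median of -0.076 (95% bootstrap interval -0.09 to -0.06). That median was taken without removing a trend with G+C, and gains of smaller segments that hold ZNF genes were not tested. After a trend with G+C, length and expression was removed, the ZNF median was 0.11 (interval 0.09 to 0.14), against 0.13 before. The 137 ZNF genes, on any chromosome, with under 1% of their 50-mers in another gene had a median of 0.11. The rise of ZNF genes as a set was thus also present where little sequence matched exactly. Near-matching sequence was not counted, and shared reads were not tested for the chromosome 19 genes alone. The ZNF median of Control 2 minus Control 1 was 0.05, so part of a shift of this size may arise between replicates, and a biological origin is a hypothesis.

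Of 11 measured beta protocadherin genes, 10 rose, with a median log2 fold change of 2.496. Genomic DNA in the libraries would raise silent single-exon genes alike, but the summed CPM of 376 olfactory receptor genes changed by a ratio of 1.06, against 5.59 for the beta genes, although olfactory receptor counts summed to only 60 to 93 per library. The 7 beta genes with under 15% of their 50-mers in another beta gene had a median of 2.496. A near-silent gene that took reads from another beta gene would show the fold of that gene. This median therefore cannot decide whether reads of a few genes were counted for the rest. One hypothesis is weaker HUSH silencing after the fall of MPHOSPH8, since HUSH is known to act on intronless genes, and it arose after the MPHOSPH8, ZNF and protocadherin values were seen. The other 342 single-exon coding genes (26 rose and 24 fell) had a median of 0.0042, above 99.94% of random lists matched on expression and G+C, which met the bound set for this hypothesis, but the distance of 0.046 from those lists compares with 0.034 in the opposite direction between the Control libraries and 0.0039 between the DHX29-KO libraries, so these data leave it open.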
